A study of Arabidopsis thaliana with 4 samples.

How the data were processed

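Genomic DNA from anti-GFP chromatin immunoprecipitation was measured in 4 samples, each a 2-colour Agilent array with ARR1:GFP material in one channel and Col-0 mock material in the other. Per the labels, DNA was amplified with random primers before labelling, which can change the relative amount of fragments in both channels. The series design gives 2 independent biological replicates and a dye exchange, and the labels do not say which 2 arrays share a replicate. Per the file headers, the deposited intensity values were made with Agilent Feature Extraction 9.5.3.1, which subtracted a spatially detrended background, applied a multiplicative detrend and scaled each channel by a linear dye factor. The deposited ratio table holds 65522 features and equals, within 1e-06, the ratio of the ARR1 to the mock processed intensity on each array. Its column medians were 1.06, 1.01, 1.06 and 1.03, so the scale was linear, no centring had been done and the direction was ARR1 over mock. Its features are numbered only up to 67003, so it covers part of the array, and it was used as an alternative. No aligner applies, and the genome build of the probe positions is not given in the sources used here.

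Control spots were left out, 1070 probes with a spot marked as an outlier on any array were left out, and spots of one probe were averaged, which left 236505 probes of 60 bases. The log2 ratio was turned to ARR1 over mock on every array with the dyes given in the labels and centred on the array's median, with no loess or quantile step. Before centring the medians were 0.06, 0.01, 0.08 and 0.02. Windows took all probes within 500 bp of a probe's centre, at least 3, and 176634 distinct windows were kept with a median of 5 probes. Enriched windows that overlapped were merged into regions, and a region is described by its highest window.

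The test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg, threshold 0.05) on the averages of dye-exchanged arrays, with n = 2 biological replicates. The 2 pairings of the arrays that the dyes allow were fitted and the larger p was kept. The p-values rest on the spread between 2 replicates and a variance shared across features. The test was tested on simulated data for 176634 windows with 200 windows shifted. Shifts of 0.25 were found in 0.5% of windows, of 0.5 in 26.5% and of 1 in 100% with the right sign, with 4, 20 and 23 false calls. Far fewer windows were shifted there than were called in the data, and the simulated windows were independent. The adjusted threshold was therefore stricter in the simulation, and smaller values can pass in the data, so these rates do not describe the data.

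The gene table is that of the TAIR10.1 assembly and was used for names and neighbours only. It gives no strand, and its positions and the probes' positions are not shared throughout. The probes avoid gene interiors, counted here as more than 300 bp from either gene end. The fit between the 2 sets of positions was therefore checked in stretches of 250000 bp. A stretch was placed where the share of probes in gene interiors was lowest within 300 bp of no shift. The share at no shift had to be well below that at other shifts. The same had to be true of the stretches on either side, which need not be placed themselves. This held for 189 of 439 stretches. Their median share of probes in gene interiors was 16.6%, against 50.2% for the median of the shifts tried. Genes were named only there, which covered 47.4% of probes and 12519 of 27444 protein-coding genes. No coordinate was converted, and genes elsewhere were not analysed here. Placing was judged from the probe tiling and not from the sequence, so a name can be wrong where the assemblies differ within a stretch.

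The planned gene feature was the promoter from 1000 bp upstream to 200 bp inside the gene. With no strand, the flanks at both ends of the gene were used, from 1000 bp outside to 200 bp inside, with at least 2 probes, and neighbouring genes can share probes. The planned profile by gene start became one by distance from the nearest gene edge in bins of 250 bp. Gene lists of cytokinin, auxin, gibberellin, ethylene, root meristem, cell cycle and control genes were fixed before the data were examined. Lists with at least 5 measured members were tested with camera (preset correlation 0.01, larger p of both pairings, Benjamini-Hochberg over lists), with an estimated correlation and with fry as alternatives. Ribosomal protein and histone genes were taken by a fixed pattern from the synonyms in the gene table, since it holds no product names.

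Motifs were searched on both strands of the probes in each peak window. They were compared with windows called neither enriched nor depleted, matched on GC content and probe number. The p-value came from 10000 binomial draws at the shares of the matched windows. In simulated sets of 500 regions with nothing planted, 4 of 100 draws passed. Named were the 20 enriched regions with the highest window above 0 on 4 of 4 arrays, the 5 most depleted regions, the highest and lowest member and up to 4 called members of each list, and ARR1, ARR5, ARR15, IAA3, GH3.17 and CKX4. Some results are left out because the items they need are withheld for evaluation. Each region was named by its nearest gene edge, since gene starts were not known.

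The alternatives were normexp signals (offset 50), no centring, loess within arrays, the deposited ratio table, only probes well above background, flagged spots kept, each pairing alone, the 4 arrays as separate values with a dye coefficient, a variance trend, adjusted p 0.01, a 1.5-fold minimum, other windows and flanks, and each array left out. Removal of a GC trend, of a trend over 1 Mb and the use of the flank with more probes were added after the data were seen. Motif tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.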

Results

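Chromatin immunoprecipitation was read on promoter microarrays to find where ARR1 lies on the genome in Arabidopsis thaliana roots. ARR1 is a type-B response regulator, a transcription factor that acts at the end of the cytokinin signalling chain. The immunoprecipitated material came from roots of 5-day-old seedlings that carried the ARR1 genomic sequence under its own promoter, fused to GFP, and the mock came from wild-type Col-0 roots treated with the same GFP antibody. Both were amplified, labelled with different dyes and hybridised together, so each array gives a ratio of ARR1 to mock. The series holds 4 arrays, made from 2 biological replicates hybridised again with the dyes exchanged, and 2 of the arrays carried ARR1 in Cy5. The arrays are called replicates 1 to 4 here. An SD with n = 4 is the spread over these arrays, and the test uses the 2 biological replicates. Between 98.3% and 99.7% of the 237976 probe spots were well above background in each channel, no spot was saturated, and the number of arrays limits the precision.

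The genes and regions most enriched in the ARR1 immunoprecipitate included ARR7, a type-A response regulator that is induced by cytokinin and dampens the signal, and the ARR1 locus itself. The highest window in ARR7 (AT1G19050, chromosome 1, 6579113 to 6579662) had a log2 ratio of 2.08 ± 0.20 (SD, n = 4), a 4.23-fold enrichment. At ARR1 (AT3G16857, chromosome 3, 5755452 to 5755908) it was 2.01 ± 0.07 (SD, n = 4), or 4.03-fold. The transgene also carries ARR1 sequence, so extra copies of the locus can raise the ARR1 ratio. The intergenic window beside GH3.17 (AT1G28130), which encodes an enzyme that conjugates auxin to amino acids, reached 1.94 ± 0.27 on chromosome 1 from 9824662 to 9825124. Beside ABCG14 (AT1G31770), a transporter that carries cytokinin from root to shoot, the value was 1.90 ± 0.22 from 11374326 to 11374829 on chromosome 1. All coordinates are those of the array files, whose genome build is not given in the sources used here.

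Of the 20 regions with the highest window, 14 lay on stretches where genes could be named, and their log2 ratios went down to 1.90. The highest of the named ones lay beside TPR2 (AT3G16830), a TOPLESS-related corepressor, at 2.20 ± 0.23 on chromosome 3 from 5730884 to 5731397. A window inside AT4G28240 on chromosome 4, from 13998391 to 13998619, followed at 2.19 ± 0.28, and the window between AT3G05775 and AT3G05770 had 2.04 ± 0.03. BBX13 (AT1G28050), a B-box protein, held 1.97 ± 0.21 inside the gene. ERF4 (AT3G15210), an ethylene response factor that represses transcription, had 1.94 ± 0.19 beside it, and SHV3 (AT4G26690), needed for cell wall organisation, 1.92 ± 0.09. Windows beside AT3G19035 and AT1G19110 each had 1.91, with SDs of 0.15 and 0.16. ADK2 (AT5G03300), an adenosine kinase, and NSP1 (AT3G16400), a nitrile-specifier protein, each had 1.90 beside them, with SDs of 0.16 and 0.11. The other 6 regions had no gene named. They included the highest of all, at 2.40 ± 0.05 on chromosome 2 from 9873717 to 9874075, a 5.28-fold enrichment. The ratios 2.15 ± 0.17 on chromosome 1 from 18327088 to 18327936 and 2.13 ± 0.17 on chromosome 3 from 17771850 to 17772243 came next among these. Then came 2.00 ± 0.41 on chromosome 2 from 8920633 to 8920919, 1.97 ± 0.16 on chromosome 1 from 21539444 to 21539823, and 1.96 ± 0.11 on chromosome 5 from 25545281 to 25545742. Each of the 20 windows was above 0 on 4 of 4 arrays and had the smallest adjusted p reached in limma, 4.57e-05.

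**Figure D1:**
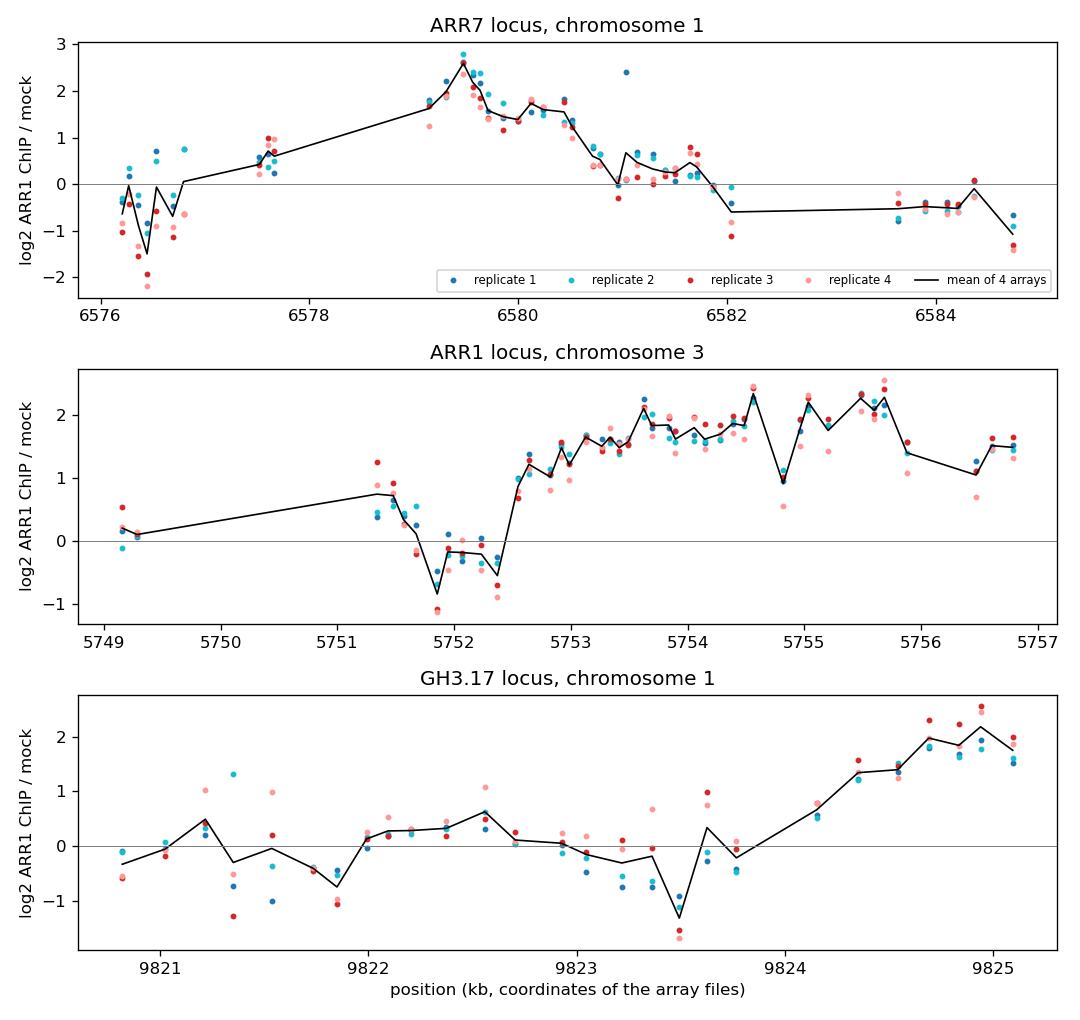
Log2 ratio of ARR1 immunoprecipitate over mock (vertical axis) at each probe against its position in kb in the array files (horizontal axis), at the ARR7, ARR1 and GH3.17 loci; points are the 4 arrays and the line their mean. The enriched window at ARR7 averaged 2.08, whereas the raised stretch at ARR1 was part of a run of 32 neighbouring probes, whose last probe lies beyond the plotted range.

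Type-A response regulators, the group of early cytokinin response genes, were both enriched where they could be measured. Only 2 of the 10 listed could be placed on the array coordinates. The flanks of ARR7 averaged 1.53 ± 0.07 (SD, n = 4), and those of ARR4 (AT1G10470) were enriched 2.46-fold, with a highest window of 1.67 ± 0.17. Both passed over all genes tested and when adjusted over the list alone (limma adjusted p = 0.000154 and 0.000167). ARR5 and ARR15, which were to be named whatever their values, lay outside the placed stretches and were not analysed here. Among 4 measured type-B regulators, ARR1 (1.84 ± 0.11) and ARR2 (0.43 ± 0.13) were enriched and ARR21 (-0.57 ± 0.16) was depleted. ARR14 had 0.24 ± 0.14, and it passed when adjusted over the list alone, which made 3 enriched members. The ARR1 flank value rests on 8 probes. The transgene also carries ARR1 sequence, to an extent not given in the sources used here, so this ratio can hold extra copies of the locus.

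Cytokinin receptors and their phosphotransfer partners were enriched at 4 of 5 members and depleted at 1, over all genes and adjusted over the list alone. AHP1 (AT3G21510) had the highest flank mean, 1.06 ± 0.07, followed by the receptor AHK3 (AT1G27320) at 0.78 ± 0.14, AHP5 (AT1G03430) at 0.51 ± 0.12 and the receptor AHK4 (AT2G01830) at 0.29 ± 0.17. AHP4 (AT3G16360) was depleted at -0.29 ± 0.15, and with the deposited ratio table it had -0.04 and did not pass. As a list they did not stand apart from other genes (limma camera, adjusted p = 0.272). Genes of cytokinin synthesis, activation and breakdown went both ways, with 5 of 14 enriched, 4 depleted and 5 not passing, the same counts adjusted over the list alone, and an adjusted p of 0.839 in camera. LOG7 (AT5G06300), which releases active cytokinin from its nucleotide, was enriched 2.15-fold, and the glucosyltransferase genes UGT76C2 and UGT76C1 had 0.94 ± 0.04 and 0.84 ± 0.06. IPT4 (AT4G24650), an isopentenyltransferase of cytokinin synthesis, was the lowest at -0.72 ± 0.17. CKX4 (AT4G29740), a cytokinin oxidase, had 0.19 ± 0.04 and did not pass (adjusted p = 0.0996). Of 3 measured cytokinin response factors, CRF4 (0.92 ± 0.06) and CRF2 (0.54 ± 0.31) were enriched, and CRF1 had 0.03 ± 0.06. Those counts were 2 enriched and 1 not passing, both over all genes and adjusted over the list alone.

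Of the fixed lists with at least 5 measured members, only the Aux/IAA genes passed in camera with its preset correlation (adjusted p = 0.0414). They did not pass with an estimated correlation (camera adjusted p = 0.845). Lists with fewer measured members, the type-A regulators and GH3 genes among them, were not tested in camera. Of the 10 measured Aux/IAA genes of the list, repressors of auxin response, 7 were enriched and 0 depleted, over all genes and adjusted over the list alone, with a median of 0.80. A group formed after the data were seen, 14 measured genes with the symbol stem IAA, overlaps the list. It held 8 enriched and 1 depleted and did not pass (camera adjusted p = 0.123 over 90 such groups). IAA17 (AT1G04250) was enriched 1.99-fold, and IAA14 (AT4G14550) had 0.97 ± 0.07, IAA3, also called SHY2 (AT1G04240), 0.87 ± 0.10, and IAA28 (AT5G25890) 0.86 ± 0.10, while IAA7 (AT3G23050) was the lowest at -0.06 ± 0.14. The list also missed the threshold with normexp signals (adjusted p = 0.196), with flanks of 2000 bp (0.253) and in 3 alternatives chosen after the data were seen: GC trend removed (0.051), 1 Mb trend removed (0.0773) and the flank with more probes (0.0823). Both measured GH3 genes of 9 listed were enriched, GH3.17 at 1.38 ± 0.08 and GH3.5 (AT4G27260) at 1.03 ± 0.14, also when adjusted over the list alone. Among 5 auxin transport genes, 3 were enriched and 1 depleted on either adjustment, that is, over all genes and adjusted over the list alone. They ran from PIN4 (AT2G01420) at 0.73 ± 0.13, LAX1 (AT5G01240) at 0.72 ± 0.07 and PIN7 (AT1G23080) at 0.36 ± 0.07 to PIN8 (AT5G15100) at -0.35 ± 0.09 (camera adjusted p = 0.632). PIN7 (0.17) and PIN8 (-0.31) did not pass with the deposited ratio table.

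Root meristem regulators were mostly near the array median. Of 9 measured, 3 were enriched and 1 depleted over all genes, and as many adjusted over the list alone: RBR1 (AT3G12280), the retinoblastoma-related protein, had 0.71 ± 0.12, MGP (AT1G03840) 0.63 ± 0.03, PLT3 (AT5G10510) 0.26 ± 0.05 and BBM (AT5G17430), the lowest, -0.32 ± 0.11 (camera adjusted p = 0.839). PLT3 and BBM did not pass with the deposited ratio table (0.23 and -0.29), and PLT3 did not with the 1 Mb trend removed (0.11), an alternative chosen after the data were seen. In the cell cycle list 1 of 4 passed on either adjustment, E2FB (AT5G22220) at 0.51 ± 0.30, and CCS52A2 was the lowest at -0.17 ± 0.15. Gibberellin genes held 3 enriched and 1 depleted of 7, or 4 and 1 adjusted over the list alone. GAI (AT1G14920), RGA (AT2G01570) and RGL2 (AT3G03450), DELLA repressors of gibberellin response, had 0.75 ± 0.13, 0.63 ± 0.18 and 0.61 ± 0.06, against -0.51 ± 0.06 at GA20OX1 (AT4G25420), an enzyme of gibberellin synthesis (camera adjusted p = 0.468). Ethylene genes held 4 enriched of 5, or 5 adjusted over the list alone. The F-box gene EBF2 (AT5G25350) was at 1.11 ± 0.16, CTR1 at 0.65 ± 0.14, EIN2 at 0.53 ± 0.15, ERF1 at 0.29 ± 0.08 and EIN3, the lowest, at 0.22 ± 0.03 (camera adjusted p = 0.144). ERF1 had 0.17 with the deposited ratio table and did not pass.

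Control genes chosen because no link to cytokinin was foreseen were enriched too in part. Of 6 housekeeping genes 3 were enriched, over all genes and adjusted over the list alone: the actin genes ACT7 (AT5G09810) at 1.08 ± 0.10 and ACT2 (AT3G18780) at 0.87 ± 0.03, and GAPC1 (AT3G04120), of glycolysis, at 0.78 ± 0.13. UBC21 had -0.04 ± 0.28. With the deposited ratio table, which covers part of the array, ACT7 had 0.25 and did not pass. The flanks of 229 genes lay above ACT7, among them both type-A regulators, ARR1, GH3.17, LOG7 and EBF2, whereas 0 of the 10 Aux/IAA genes of the list did. Photosynthesis genes held 0 enriched and 1 depleted of 3 on either adjustment, with LHCB1.3 the highest at 0.20 ± 0.21 and LHCB1.1 at -0.44 ± 0.05, and their median (0.16) and mean (-0.03) differed in sign. Of 20 ribosomal protein genes, 3 were enriched and 5 depleted, or 3 and 4 adjusted over the list alone, from PSRP3/2 at 0.38 ± 0.14 to PRPL11 at -0.61 ± 0.13. Of 7 histone genes, 2 were enriched and 2 depleted, or 3 and 2 adjusted over the list alone, from H2AXA at 0.61 ± 0.09 to HTA2 at -0.36 ± 0.10, which had -0.15 with normexp signals and did not pass. The adjusted p in camera was 0.272 for the housekeeping list, 0.272 for ribosomal proteins and 0.839 for histones. Random lists of genes matched on mean signal were drawn 10000 times. Against these, the list median lay at percentile 60 for housekeeping, 47.2 for histones, 90.1 for photosynthesis and 0.77 for ribosomal proteins. It lay at 100 for Aux/IAA and GH3, 99.7 for type-A regulators, 96.5 for ethylene and 95.8 for receptors and phosphotransfer partners. For auxin transport it was 95, response factors 94.7, cytokinin metabolism 90.5, gibberellin 85.4, type-B regulators 76.5, cell cycle 62.2 and root meristem 42.4. Mean signal includes the ARR1 channel, so matching on it can remove part of an enrichment.

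**Figure D2:**
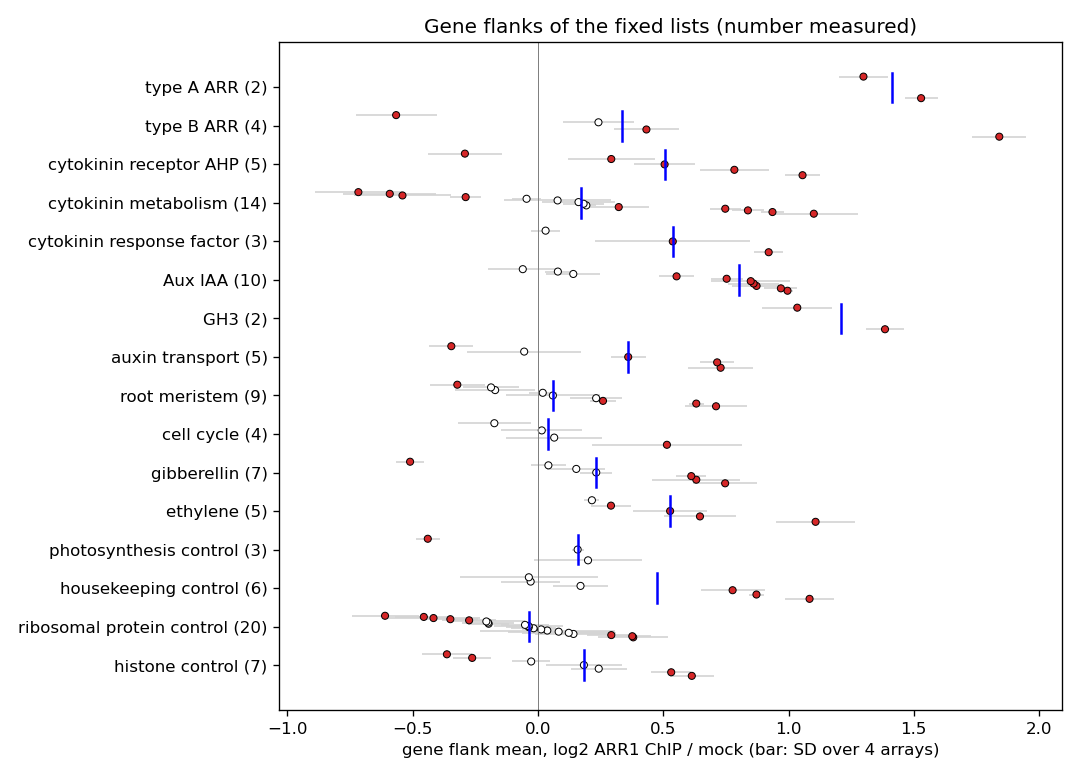
Mean log2 ratio of ARR1 immunoprecipitate over mock over the gene flanks (horizontal axis) for each measured member of the fixed lists (vertical axis, number measured in brackets); bars are the SD over 4 arrays, filled points passed an adjusted p of 0.05 and blue lines are list medians. The type-A regulator ARR7 lies at 1.53, and the housekeeping genes reach 1.08.

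Regions depleted in the ARR1 immunoprecipitate were common. The lowest window, on chromosome 2 from 4778663 to 4778865, had a log2 ratio of -2.06 ± 0.71 (SD, n = 4). The next were -1.92 ± 0.58 on chromosome 4 from 4730140 to 4730975, -1.90 ± 0.92 on chromosome 1 from 15438129 to 15438552, and -1.85 ± 0.72 on chromosome 5 from 11234853 to 11235251. The window between AT3G07840 and AT3G07850 on chromosome 3, from 2503557 to 2503868, had -1.78 ± 0.31. These 5 windows were below 0 on 4 of 4 arrays, and the first 4 varied more between arrays than any of the 20 highest regions did.

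Over the whole array, 53469 of 176634 windows were enriched and 50917 depleted, which merged into 9877 and 10372 regions with median lengths of 995 and 937 bp. Zero is the array median, so the near-equal counts follow in part from the centring. Strong values were less even: 9714 windows were enriched and 3495 depleted at least 2-fold, and 649 against 73 at a log2 ratio of at least 1.5. Of single probes, 47379 of 236505 were enriched and 39188 depleted. Of 12049 genes with measured flanks, 4360 were enriched and 2599 depleted, and 344 and 42 of these by at least 2-fold. Enriched genes made up 62.7% of the gene calls, and 51.6% after a loess normalization within arrays. That loess step cut the enriched genes to 3124. Across windows the mean log2 ratio correlated with the mean signal of both channels (Pearson's r = 0.577), and less with GC content (r = -0.135). Both channels also enter the ratio, so the ratio and the mean signal are not independent. The fixed lists and named genes were not rerun with loess, so how far their calls follow signal is not known.

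The type-B response regulator core AGATT was not in detectable excess in enriched regions over matched windows, whereas the G-box CACGTG, an element bound by bZIP and bHLH factors and included as a control, was in excess. The G-box was found in the probes of 3.77% of the peak windows of all enriched regions and in 1.31% of windows matched on GC content and probe number (test on binomial draws, adjusted p = 0.0006). In the 500 highest regions it was in 9.20% against 1.44%, a ratio of 6.39 (adjusted p = 0.0012). The unadjusted p of 0.0002 behind both is the smallest that the draws can give. The AGATT core was in 69.6% of peak windows against 70.5% of matched ones (adjusted p = 0.094), and in 72.6% against 71.2% in the 500 highest regions (adjusted p = 0.771). Against windows that were not matched, where it stood at 77.2%, the core was less frequent (adjusted p = 0.0002). The extended form AGATHY had 72.5% against 73.0% (adjusted p = 0.305), GGATT 34.2% against 35.0% (adjusted p = 0.13) and AGATCTT 4.60% against 4.62% (adjusted p = 0.928). TTAGA, a control with the bases of the core in another order, was slightly less frequent, at 63.3% against 65.1% (adjusted p = 0.0006). Only the bases on the probes were searched. In simulated sets of 500 regions, AGATT was planted in a random 10%, whether or not they already held it, and 20 of 100 draws were called. Since most windows hold AGATT already, this added an excess smaller than 10 points. An excess that small in the 500 highest regions would often be missed, and the power for a larger one was not tested.

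**Figure D3:**
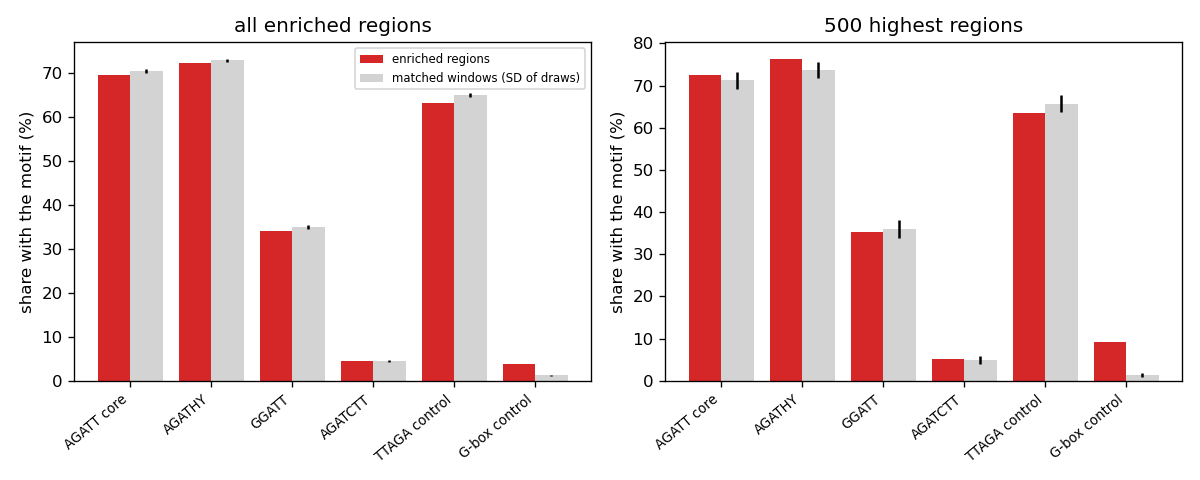
Share of windows with each motif in percent (vertical axis) for the peak windows of enriched regions and for matched windows called neither enriched nor depleted (horizontal axis lists the motifs). Bars start at 0 and error bars are the SD of the random draws. The G-box rises from 1.44% to 9.20% in the 500 highest regions, while AGATT stays at 71.2% and 72.6%.

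Regions near gene ends had slightly higher ratios than gene interiors. In the placed part, probes up to 250 bp outside a gene edge averaged 0.14 ± 0.01 (SD, n = 4), and probes from 500 to 750 bp inside averaged -0.06 ± 0.08. The gap exceeded the spread between arrays and was not tested further. Across windows the 4 arrays correlated with Pearson's r from 0.839 to 0.964, and replicates 1 and 2 (0.962) and replicates 3 and 4 (0.964) were closest. Windows are not independent replicates. The sign was shared by all 4 arrays in 79.0% of windows.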

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

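The rule for values set apart, Dixon's limit, was fixed before the data were examined, and no such test was chosen after a result was seen. Of 98 values measured on the 4 arrays, 4 had 1 array set apart from the others by more than Dixon's limit, and chance flags about 1 in 20 groups of independent values. The arrays are dye exchanges of 2 biological replicates and are not independent, so the rate by chance is not known here. At the unnamed region on chromosome 3 from 17771850 to 17772243, replicate 4 (1.88) lay below the other arrays (2.22, 2.24 and 2.18), and the gap was 0.843 of the range. At AHP1, replicate 3 had 1.16 against 1.02, 1.02 and 1.02, a gap of 0.965 of the range. At CRF4, replicate 4 had 0.84 against 0.96, 0.94 and 0.94, a gap of 0.853. The median ARR1 signal of replicate 4 was 1317 against 1406, 1411 and 1413 on the other arrays, a gap of 0.929. The regions at AHP1 and CRF4 stayed above 0 on 4 of 4 arrays.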

How the results depend on the processing

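Removal of a GC trend, removal of a trend over 1 Mb and the flank with more probes were chosen after the data were seen. Enriched windows, depleted windows, enriched probes and enriched gene flanks stayed within 1.5 times their main counts under most alternatives. With the deposited ratio table they fell to 4031, 3416, 12626 and 2646, since it holds fewer features, and 13 of the 20 named regions remained. The first pairing alone, of replicates 1 with 2 and 3 with 4, gave the main counts. The second joins arrays that correlated less across windows (1 with 4 at r = 0.839, 2 with 3 at r = 0.868). Alone, the second pairing gave 81565 depleted windows and 94219 enriched probes. An adjusted p of 0.01 gave 22764 enriched probes. A 1.5-fold minimum gave 32518 enriched and 24681 depleted windows and 1809 flanks, by construction. With 1 array left out the ranges were 55695 to 58558 enriched and 52823 to 57949 depleted windows, 49023 to 59565 probes and 4777 to 4878 flanks. These fits took the remaining arrays as separate values with a dye coefficient, so dye-exchanged arrays counted as replicates. They differ from the main test in more than the array left out, which also holds for the calls gained below. The number of lists that passed, 1, was 0 with an estimated correlation, with normexp, with flanks of 2000 bp, with the GC or 1 Mb trend removed and with the flank with more probes. With fry, which tests a list against no change and not against other genes, 5 passed, the histone controls among them. The list direction turned for cytokinin metabolism with normexp (adjusted p = 0.835) and with the flank with more probes (0.949), for root meristem with the 1 Mb trend removed (0.92) and for histones with the flank with more probes (0.768). CRF1 had -0.00723 with normexp and -0.00292 to 0.0648 with 1 array left out, UBC21 had 0.12 with normexp and -0.16 to 0.0886, and IAA7 had -0.13 to 0.00606. None of these 3 genes passed in the main analysis. A call was lost in at least 1 alternative at 11 other named genes: with the deposited ratio table at ACT7, AHP4, PIN7, PIN8, ERF1, BBM, PLT3 and HTA4, with normexp at HTA2 and RPL18AA, and with the 1 Mb trend removed at RPS15A, PLT3 and HTA4, the last also with the GC trend removed. A call was gained at 5, namely CRF1 with the 1 Mb trend removed, and EIN3, LHCB1.3, CCS52A2 and CKX4 with 1 array left out. Of 6 motifs 2 passed, 6 with an unmatched background (AGATT difference -7.57 points) and 1 in the 500 highest regions, where AGATT, AGATHY and AGATCTT turned to 1.38, 2.66 and 0.322 points. Beyond what construction explains, the cause was not tested. No paired analysis was possible because the labels give no replicate numbers and hold a single group, so there is no second group to pair with, and the pairings above join dye-exchanged arrays within it. Signal well above background at 98.3% of spots or more left few probes limited by depth.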

Other observations

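The gene families, the symbol groups, the hexamer scan, the 3 patterns weighed and the tests of dye bias and of the ARR1 locus were chosen after the values were seen. So were the tests of GC content and of the 1 Mb trend, which replaced counts of depleted windows, while the limits of both G-box tests were set before their values.

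Gene families outside the fixed lists also differed. Among 90 groups of genes that share a symbol stem, with at least 8 measured members each, CIPK kinases, which act in calcium signalling, were enriched at 11 of 13 members with a median log2 ratio of 0.56 (camera adjusted p = 0.0348, and adjusted p = 0.961 with an estimated correlation). WRKY transcription factors, many of them tied to defence, were enriched at 19 of 27 and depleted at 2, with a median of 0.50 (camera adjusted p = 0.0348, and 0.961 with an estimated correlation), and WRKY53 had 0.90. Genes with the stem LCR, used for small cysteine-rich proteins, were depleted at 17 of 37 and enriched at 4 (camera adjusted p = 0.00548). Those with the stem SCRL, also used for such proteins, were depleted at 9 of 14 and enriched at 2 (camera adjusted p = 0.0348). The groups rest on the symbol alone, so they can hold unrelated genes. No group passed with an estimated correlation (adjusted p = 0.961).

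Of the 229 genes whose flanks lay above the highest housekeeping control, 6 are named here, chosen after their values were seen and with no test of a shared function. The flanks of CBF1, a cold response regulator, averaged 1.75 ± 0.10 (SD, n = 4), those of the catalase gene CAT1 1.70 ± 0.10, of JAZ1, a repressor of jasmonate response, 1.48 ± 0.09, and of the root beta-glucosidase gene PYK10 1.54 ± 0.08. The flanks of the corepressor gene TPL had 1.59 ± 0.23 and those of the cellulose synthase gene CESA1 1.59 ± 0.14. All of these passed in limma.

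Windows in 9 bins of 1 Mb averaged below -0.5, namely chromosome 2 from 3000001 to 5000000, chromosome 3 from 12000001 to 15000000, chromosome 4 from 3000001 to 5000000 and chromosome 5 from 11000001 to 13000000. Their mean was -0.65, with -0.59 in replicates 1 and 2 and -0.71 in replicates 3 and 4. It was -0.62 with the GC trend removed and -0.64 without probes that share 20 bases with another probe. Probes that share 20 bases made up 7.48% there and 3.96% elsewhere, and mean GC was 29.4% and 27.8%. GC content and shared probes had first been weighed as causes of these low bins, both values went against them, and that pattern was then dropped in favour of the G-box to keep to 3.

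The G-box excess in the 500 highest regions was the strongest of 2080 hexamers, and CACGTG, ACGTGG and ACACGT ranked first, while GATACG (read as CGTATC), which holds the GAT of the type-B core, ranked 8 at 8.80% against 3.75% (adjusted p = 0.0122). Base composition would give a like excess to other palindromes of the same bases, but the median ratio of 23 such palindromes was 1.17, the highest, ACGCGT, had 4.30, and CACGTG had 6.36. Place relative to gene ends would remove the excess once the distance was matched, but the ratio was still 5.12 in 272 placed regions. These values argue against both as the whole cause. Binding by another factor at the same promoters, open chromatin at active promoters and an indirect contact of ARR1 may each contribute and were not tested.

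The many windows below the array median were also weighed. Dye effects cancel in the dye-balanced averages by construction, and the dye contrast had an SD of 0.129 of that of the mean ratio, where a value of 0.5 or more would have pointed to dye bias. A first test, the number of depleted windows with the GC trend removed (50981) or the 1 Mb medians removed (47405), decides nothing, because the centring largely fixes that number. Of the depleted windows, 96.1% were still called with the GC trend removed and 77.7% with the 1 Mb medians removed, so neither trend is the whole cause, and the 1 Mb trend accounts for part of the calls. Centring on the median fixes where 0 lies, and a difference in chromatin recovery between the ARR1:GFP and Col-0 samples, or in amplification, remains open.

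The ARR1 locus was raised along 32 neighbouring probes above a log2 ratio of 0.75, with a mean of 1.63. All but the last of them lay between 5752517 and 5756814, and the last ended at 5761200 after a gap with no probe used. The extent of the transgene is not given in the sources used here, and these probes do not cover the locus in full. Extra copies in the transgene line would raise the part of the locus that the transgene carries. The test of this was changed after its result was seen: the first one took the lowest probe of the merged ARR1 region, which was -0.54 with 7.97% of 113 other regions lower, and by its own prediction that went against extra copies. It was replaced by the length of the run, because the merged windows reach past the run's edge, first with a limit of 99%, which the run would have passed, since it was longer than 99.9% of 4647 runs. Once 2 other runs were seen to be longer, with up to 35 probes, the limit was raised to the longest run of all, which ARR1 did not reach. That limit was set with the rank of the ARR1 run already known, so this test decides nothing. Extra copies and binding of ARR1 to its own gene could not be told apart, and no biological explanation was tested.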
